A study of Danio rerio with 29 samples.

How the data were processed

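The deposited files held 2 count tables of zebrafish RNA, one of whole brains and one of bodies from which the brain had been taken, with 32520 genes each. The values were raw counts of reads per gene, per the labels and as tested on the files: all were whole numbers, and the totals differed between libraries. RNA had been selected for poly(A) tails and read in pairs of 150 bp on an Illumina HiSeq. The submitters' processing notes name STAR and the genome builds GRCz11 and GRCz10 without saying which build was used for what. The program that counted the reads, the annotation release and the strand setting are not given in the sources used here. The authors had applied no normalization to the deposited counts.

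The labels place the 29 libraries in 6 groups: wild type (WT), a line labelled CCSER1_P471 (M) and a line labelled CCSER1_S48Y* (S), each in both tissues. Fish of both lines were homozygous adults, and the wild-type fish were siblings of mutants, although the labels do not say of which line. Sex, clutch, pooling and sequencing batch are not labelled, and the labels do not say that each library was a separate animal, so the p-values measure only the spread between libraries. Replicate numbers were not used as pairs in the main fits. Correlations of residuals between libraries of like number ran from -0.2744 to 0.4782 in bodies (median 0.1258, 10 of 18 above 0.1). In brains they ran from -0.2515 to 0.1246 (median -0.019). A number was the best match of both libraries in only 2 of 18 body pairs and 0 of 10 brain pairs. Every pair of WT and M bodies had a positive value, from 0.08354 to 0.4782, so a factor shared by number is not excluded there. No library duplicated another in 15 brain and 45 body pairs within groups.

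Genes were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, robust fit, TMM factors, the default filter on low counts), with all 3 groups of a tissue in 1 fit. Genes with a Benjamini-Hochberg adjusted p below 0.05 were called. The fit kept 18733 genes in brain and 20240 in body. TMM factors ran from 0.9665 to 1.03 in brain and from 0.8574 to 1.084 in body, and the biological coefficients of variation were 0.202 and 0.292. Every adjusted p of a gene is from edgeR, fold changes are log2 values from the same fit with their standard errors (SE), and levels are CPM (counts scaled to library totals) after TMM scaling, as mean ± SD. Differences between tissues were tested as an interaction in 1 fit of all 29 libraries over 22442 genes.

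The choices above, 26 gene lists, 16 marker lists of cell types and organs, the comparisons and the rule for named genes were fixed before the data were examined. Lists with 5 or more tested members were tested with camera of limma 3.58.1 (preset correlation 0.01, adjusted over the lists of a comparison), 37 in brain and 41 in body; camera with an estimated correlation and fry stood beside it. A camera p asks whether a list moved relative to all other genes, while fry asks whether its members moved, on balance, one way, without comparing them with other genes. Counts of called members are given over all genes tested and adjusted over the list alone. The genes named are ccser1 and its paralogs, the 12 genes per direction with the smallest adjusted p in each comparison with WT (6 between lines and between tissues), the 10 genes called in both lines with the smallest larger adjusted p, and up to 4 members per list with the smallest unadjusted p. Genes with only clone names were passed over, and some genes that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen. Symbols are those of the supplied name table, which gives many zebrafish genes the symbol of the human orthologue in capitals; ccser1 is listed there as CCSER1.

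Positions came from a supplied RefSeq table matched by symbol, which placed 17212 genes on 25 chromosomes in gene order. A window of 5 Mb around ccser1 was not used here, because coordinates of the build used for counting were not at hand; the 100 nearest tested genes took its place. Chromosome shares were compared with Fisher's exact test, two-sided. Where a group had 0 counts of a gene, the fold is a bound against a floor of 3 counts over the group; with 1 to 3 counts the ratio of CPM has a 95% interval that covers counting error only. A self-test on simulated data recovered 55.7% to 70.1% of genes changed 2-fold and 81.6% to 94.9% of those changed 4-fold in the comparisons within a tissue, against 27.6% and 71.4% for the interaction.

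Alternatives tried were DESeq2 1.42.0, RLE factors, no filter, a filter at 1 CPM, a fit that is not robust, only the groups compared, the replicate number as a block, each library left out in turn, a minimum change of 2-fold, leaving out the ccser1 chromosome, and for bodies the ovary list's score as a covariate. Added after seeing the data were fits without libraries that stood apart and the 100 nearest genes. No library was left out of the values reported.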

Results

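RNA was counted per gene in 29 libraries of adult zebrafish, 11 from whole brains and 18 from bodies without the brain. The fish were wild type (WT) or homozygous for 1 of 2 CRISPR alleles of ccser1, here called M (CCSER1_P471) and S (CCSER1_S48Y*). Brains gave 3 WT, 4 M and 4 S libraries, and bodies gave 6 of each. Total counts ran from 7445865 to 9521735 in brain libraries and from 9450422 to 11674882 in body libraries. The 10 most abundant genes took 6.537% to 7.906% of the counts in brains and 11.23% to 16.4% in bodies. The comparisons ask which transcripts differ when ccser1 is mutated, in which tissue, and whether both alleles do alike; the series title also names neurodevelopment and the response to alcohol as interests.

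The transcript of ccser1 was lower in the bodies of both lines, and did not pass the test in brains. Bodies held 4.61 ± 1.21 CPM (SD, n = 6) in WT, 2.85 ± 0.753 in M and 2.83 ± 0.972 in S, a fall of 0.69 on the log2 scale in M (SE 0.243, adjusted p = 0.0341) and of 0.70 in S (SE 0.242, adjusted p = 0.0299). In 4 of 6 M and 5 of 6 S bodies ccser1 lay below every WT body. These calls were fragile: the M call was lost without WT body 1 (adjusted p = 0.0748), 2 (0.0569) or 4 (0.0878) or M body 2 (0.0732), 3 (0.0513) or 6 (0.0764). The S call was lost without WT body 1 (0.0595), 2 (0.0502) or 4 (0.0767) or S body 2 (0.0543), 3 (0.064) or 6 (0.0677). With the ovary score as a covariate ccser1 was at -0.97 in M (SE 0.512, adjusted p = 0.702) and -0.94 in S (SE 0.459, adjusted p = 0.474), so the calls ended with a larger SE and not with a smaller change. Without the 5 bodies low in the growth hormone gene gh1 it was at -0.73 in M (adjusted p = 0.132) and -0.78 in S (adjusted p = 0.0749). Brains held 9.4 ± 1.79 CPM of ccser1 (SD, n = 3) in WT, 8.38 ± 1.54 (n = 4) in M and 10.7 ± 2.17 (n = 4) in S, log2 changes of -0.165 (adjusted p = 0.666) and 0.19 (adjusted p = 0.61). Neither the difference between tissues (-0.56, adjusted p = 0.313, in M and -0.95, adjusted p = 0.0805, in S) nor that between M and S (adjusted p = 0.263 in brain and 0.99 in body) passed. Without S body 5 the difference between tissues passed in S (adjusted p = 0.0313). Of its paralogs, CCSER2 rose in S bodies by 0.41 (SE 0.104, adjusted p = 0.00541), and ccser2b passed in no comparison. The CCSER2 value was 0.04 with the ovary covariate (SE 0.154, adjusted p = 0.956) and 0.36 without those 5 bodies (adjusted p = 0.0668). CCSER2 also passed in M bodies, at 0.29 (adjusted p = 0.0397), a call that 7 of the 18 fits with 1 library left out did not make. It was at -0.16 there with the ovary covariate (adjusted p = 0.932) and at 0.13 without those 5 bodies (adjusted p = 0.58).

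**Figure D1:**
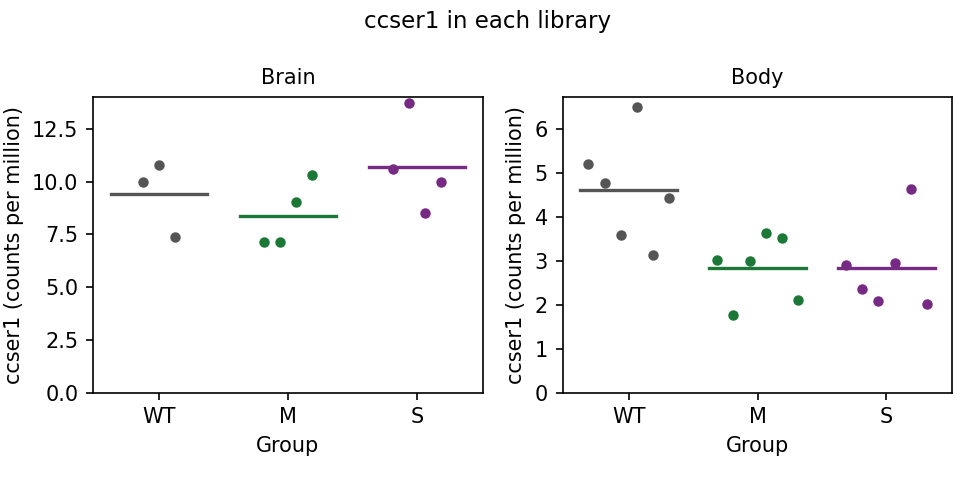
Level of ccser1 in CPM in each brain and body library (points), with the group mean (line). Bodies of M (2.85 CPM) and S (2.83 CPM) lie mostly below WT bodies (4.61 CPM), while brain groups overlap.

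**Figure D2:**
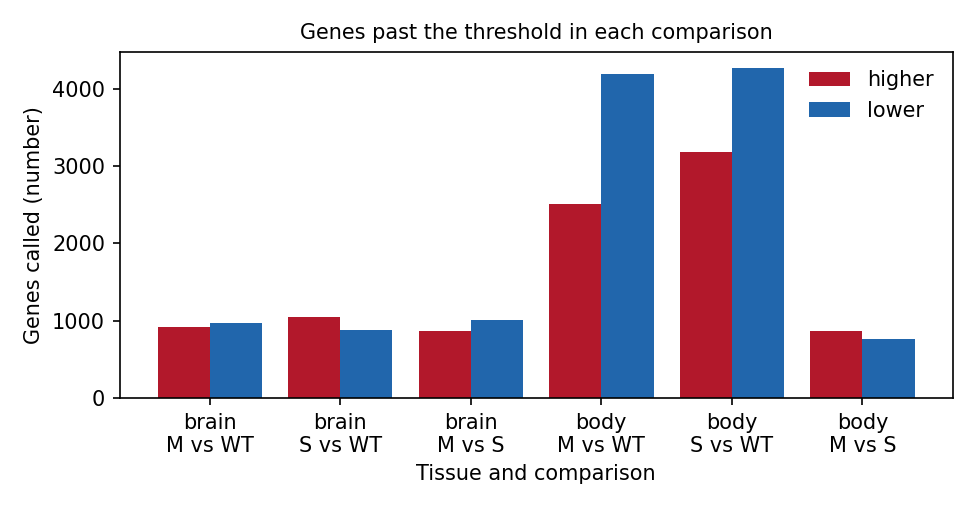
Number of genes called higher (left bars, red) and lower (right bars, blue) in each comparison at an adjusted p below 0.05. Bodies against WT gave the most, 6696 in M and 7445 in S.

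In M brains, genes of the photoreceptor cascade rose. The arrestin gene saga went from 1.94 ± 0.675 CPM (SD, n = 3) in WT to 45.1 ± 7.63 (n = 4) in M, a rise of 4.52 on the log2 scale (SE 0.294, adjusted p = 7.71e-06). With it rose rbp3, which codes for a retinoid-binding protein (3.75), PDE6H (4.26) and PDE6C (4.04), subunits of the cone phosphodiesterase, the retinol dehydrogenase rdh5 (4.63), the recoverin gene rcvrnb (3.39), unc119c (4.99) and the cone arrestin ARR3 (3.81). The photoreceptor transcription factor crx was 42.6 times its WT level (95% counting interval 14.4 to 209). Outside this group GFM2, a mitochondrial elongation factor, rose by 2.19 (SE 0.108, adjusted p = 7.48e-08), from 15.6 ± 0.431 to 71.4 ± 5.51 CPM. The relaxin receptor RXFP1 rose by 1.31, WDR81 by 1.02, cnot6b by 1.89 and ppdpfa by 2.48. The neurotrophin BDNF fell from 96.2 ± 1.69 to 55.2 ± 5.82 CPM, by 0.80 (SE 0.0836, adjusted p = 6.45e-05), and UCN, the urocortin gene, by 0.85. Also lower were gpr3 (-0.89), RERGL (-1.002), CAP1 (-2.73), TMEM101 (-2.01), the cytochrome P450 cyp2p7 (-2.335) and ANXA6, from 21.8 ± 9.76 to 0.14 ± 0.14 CPM (-7.095). The thioesterase PPT2 stood at 9.06 ± 1.42 CPM in WT and at 0.0266 ± 0.0531 in M, 313 times lower (95% counting interval 55.6 to 12400), and znf1156 was 120 times lower (21 to 4800). In monoamine pathways TPH2, of serotonin synthesis, rose by 0.68 and TH, of dopamine synthesis, fell by 0.79.

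Of the sterol pathway 12 of 25 measured members were lower in M brains and none higher (15 lower adjusted over the list alone; adjusted p = 5.6e-13, and adjusted p = 0.117 with an estimated correlation), with SQLE at -2.03, MSMO1 at -1.31, FDPS at -0.99 and IDI1 at -0.71. Of myelin genes 8 of 15 were lower (10 lower and 1 higher adjusted over the list alone; adjusted p = 2.63e-09, and adjusted p = 0.242 with an estimated correlation): mbpb went from 196 ± 25.5 to 97 ± 15.3 CPM (-1.01), cldnk fell by 1.33, plp1b by 1.09 and UGT8 by 0.68. Of the nuclear genes of oxidative phosphorylation 24 of 71 were lower (43 adjusted over the list alone; adjusted p = 6.64e-15, and adjusted p = 0.416 with an estimated correlation), among them NDUFB5 (-0.42) and UQCRQ (-0.57). Of cytosolic ribosomal proteins 22 of 78 were lower (48 adjusted over the list alone; adjusted p = 5.76e-14, and adjusted p = 0.466 with an estimated correlation), among them RPL38 (-0.47) and RPS23 (-0.46). Among orthologues of neurodevelopmental disease genes, 13 of 60 were higher and none lower (19 and 0 adjusted over the list alone; adjusted p = 2.2e-06, and adjusted p = 0.242 with an estimated correlation), such as CACNA1C (0.46). Glia markers fell in 5 of 15 (6 adjusted over the list alone; adjusted p = 0.000311, and adjusted p = 0.117 with an estimated correlation), with S100B at -0.66 and FABP7 at -0.52. Oxidative-stress genes fell in 9 of 26 (11 adjusted over the list alone; adjusted p = 1.93e-05, and adjusted p = 0.172 with an estimated correlation), with gpx3 at -0.87. Among 41 clock genes 3 were higher, such as CLOCK (0.86), and 6 lower, such as cry3a (-0.52). The count was 3 and 13 adjusted over the list alone (adjusted p = 0.000592, and adjusted p = 0.555 with an estimated correlation). M brains were split here: clock genes summed to 6680, 5710 and 6310 CPM in M brains 1, 2 and 3. In M brain 4 they summed to 8910 CPM, above every WT brain (8180 to 8520). Chaperone genes fell in 6 of 28 and rose in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.00659, and adjusted p = 0.407 with an estimated correlation), with HSPE1 at -0.67 and hsf1 at 0.60. Markers of neurons fell in 7 of 16 and rose in 1 (adjusted p = 0.00695, and adjusted p = 0.407 with an estimated correlation), with SNCG at -1.29. Of the alcohol lists, metabolism had 1 member higher and 4 lower of 31 and receptors and channels 4 higher and 2 lower of 37, with KCNJ9 at 0.65; neither list passed (adjusted p = 0.15 and 0.699).

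In M brains 1895 of 18733 genes were called, 923 higher and 972 lower, with a median absolute log2 change of 0.539, and 205 and 216 of them changed at least 2-fold. The count was 1128 without WT brain 2, 1060 without WT brain 3, 1224 without M brain 1, 1075 without M brain 3, and 1186 when only WT and M entered the fit. Of 37 lists, 17 passed: 4 higher and 13 lower. The photoreceptor list was strongest, with 16 of 18 members higher and none lower (17 and 1 adjusted over the list alone), a median change of 3.56 and a sum of 47.57 ± 3.85 CPM in WT against 304.1 ± 54.7 in M (adjusted p = 4.05e-45). Its call held with an estimated correlation (adjusted p = 0.0403), and it alone. Of 36 matched members of the photoreceptor list 18 passed the filter on low counts. That filter can keep a gene low in WT through high mutant libraries, so 16 of 18 is not the share of the whole list. In a pineal gland list written after the results were seen, aanat2 (1.04 CPM in WT, 9.76 in M) and ASMT (0.756, 17.6) rose too. In that list asmt2 did not rise (10, 7.42).

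In S brains genes of the photoreceptor cascade rose as well. The arrestin saga reached 58.1 ± 13.7 CPM (SD, n = 4), a rise of 4.89 (SE 0.294, adjusted p = 5.89e-06), PDE6H rose by 4.74, PDE6C by 4.365, rcvrnb by 4.03, rbp3 by 3.31, RCVRN by 4.31 and unc119c by 5.39. The factor crx was 60.1 times its WT level (95% counting interval 20.3 to 293) and rcvrna 93.3 times (16.5 to 3710). One of the genes listed as PTK2B, a tyrosine kinase, rose from 1.24 ± 0.406 to 23 ± 0.53 CPM, by 4.196 (SE 0.247, adjusted p = 4.16e-07), asip2b, of the agouti family, by 1.105 and the clock gene PER3 by 0.90. The growth factor gdf3 fell from 36.9 ± 8.1 to 4.35 ± 0.756 CPM, by 3.08 (SE 0.186, adjusted p = 4.16e-07), and cbln13, of the cerebellin family, by 5.15. Also lower were CAP1 (-2.51), WDR41 (-0.77), SPECC1L (-0.89), ZBTB11 (-1.02), map1sb (-1.06), syt13 (-0.61), DHPS (-0.84) and PDHB, of the pyruvate dehydrogenase complex (-0.58). BDNF fell by 0.39 (adjusted p = 0.00944), a smaller estimate than in M brains, with no test of BDNF between the lines given here.

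Of the nuclear genes of oxidative phosphorylation, 52 of 71 were lower in S brains and none higher (67 adjusted over the list alone; adjusted p = 3.28e-35, and adjusted p = 0.216 with an estimated correlation), such as COX5A (-0.69), cox7b (-0.58) and cox8b (-0.53). Ribosomal proteins were lower in 10 of 78 (22 adjusted over the list alone; adjusted p = 1.43e-09, and adjusted p = 0.837 with an estimated correlation), with RPL38 at -0.33; its own call was lost without WT brain 1 or 3 or S brain 2 or 4. Neurodevelopmental disease genes were higher in 13 of 60 (19 higher and 1 lower adjusted over the list alone; adjusted p = 1.31e-05, and adjusted p = 0.299 with an estimated correlation), with SHANK3 at 1.06 and syngap1b at 0.33. Glutamate signalling had 6 of 37 members higher and none lower (6 adjusted over the list alone; adjusted p = 0.000632, and adjusted p = 0.216 with an estimated correlation), with the receptor genes grin2db at 0.86 and GRIA1 at 0.48. Chaperones were lower in 8 of 28 (11 lower and 1 higher adjusted over the list alone), with HSPE1 at -0.63 and STIP1 at -0.33, and oxidative-stress genes in 8 of 26 (11 adjusted over the list alone), with SOD1 at -0.40. Both lists had adjusted p = 5.49e-05, and adjusted p = 0.216 with an estimated correlation. Sterol synthesis had 0 of 25 members called and myelin 1 of 15, olig1 at -0.85. Of the alcohol lists, metabolism had 2 members lower of 31 and receptors and channels 3 higher and 1 lower of 37, with KCNJ9 at 0.85; neither passed (adjusted p = 0.314 and 0.429).

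In S brains 1935 genes were called, 1048 higher and 887 lower, with a median absolute log2 change of 0.526, and 239 and 134 of them changed at least 2-fold. The count was 895 without WT brain 3, 1131 without S brain 2 and 1208 without S brain 4. S brain 3 held far more muscle and epidermis transcripts than the other S brains, and without it 1686 genes were called. Of 37 lists 8 passed, 4 in each direction. The photoreceptor list, with 17 of 18 members higher (17 higher and 1 lower adjusted over the list alone), a median of 3.58 and a sum of 346.7 ± 93.8 CPM, had adjusted p = 1.94e-52, and its call held (adjusted p = 0.0323 with an estimated correlation). These 18 are the members, of 36 matched, that passed the filter on low counts. A gene low in WT can pass it through high mutant libraries, so 17 of 18 is not the share of the whole list. Of the pineal genes, aanat2 (1.04 CPM in WT, 7.52 in S) and ASMT (0.756, 19.9) rose too, and asmt2 (10, 8.17) did not. GABA signalling passed at 0.046, with 5 members higher and 1 lower of 27 (6 and 1 adjusted over the list alone), and had adjusted p = 0.49 with an estimated correlation. That call was lost without WT brain 1 (adjusted p = 0.139), M brain 1 (0.0586), 2 (0.0518) or 3 (0.0571), or S brain 1 (0.0592), 2 (0.156) or 4 (0.0515).

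**Figure D3:**
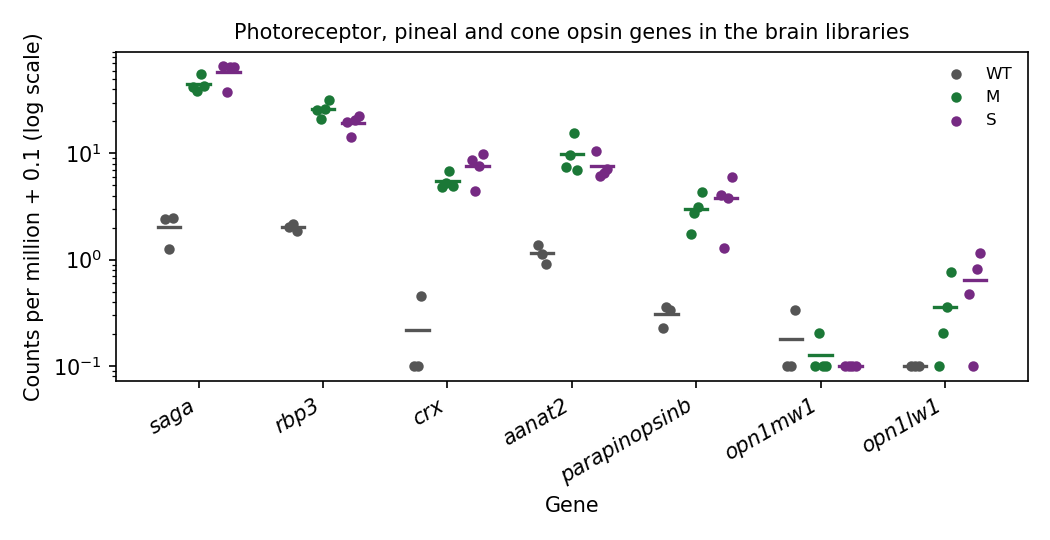
Levels of 7 genes of photoreceptors and the pineal gland in each brain library, in CPM plus 0.1 on a log axis. The arrestin saga lies near 1.94 CPM in WT and at means of 45.1 and 58.1 in M and S. The cone opsins stay low, opn1mw1 at means of 0.0781, 0.0266 and 0 CPM in WT, M and S, and opn1lw1 at 0, 0.259 and 0.539.

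The 2 lines also differed from one another in brains. GFM2 was higher in M than in S by 2.46 (SE 0.0982, adjusted p = 3.81e-09), gdf3 by 2.199, PIP5KL1 by 1.91, ZBTB11 by 1.28, SPECC1L by 1.12 and ACADSB, an enzyme of branched-chain acid breakdown, by 1.05. The same PTK2B gene was lower in M by a log2 change of -4.101 (SE 0.216, adjusted p = 9.5e-08), ANXA6 by -7.14, ppt2a.3 by -6.21, rca2.2 by -2.45 and ENPP5 by -0.81, and PPT2 was 364 times lower (95% counting interval 64.9 to 14400). Sterol genes were lower in M in 10 of 25 (15 adjusted over the list alone; adjusted p = 3.49e-10, and adjusted p = 0.526 with an estimated correlation), with SQLE at -1.76 and SC5D at -1.32. Myelin genes were lower in 7 of 15 (8 adjusted over the list alone; adjusted p = 0.000147, and adjusted p = 0.911 with an estimated correlation), with mbpb at -0.69 and cldnk at -0.85. Clock genes were lower in 9 of 41 and higher in 1 (15 and 1 adjusted over the list alone, adjusted p = 4.99e-07, and adjusted p = 0.911 with an estimated correlation), with tefb at -0.36 and ciartb at -0.49. They summed to 8910 CPM in M brain 4, near the 8930 to 9740 of S brains, and to 5710 to 6680 in the other M brains. Oxidative phosphorylation was higher in 5 of 71 (5 adjusted over the list alone; adjusted p = 8.67e-05, and adjusted p = 0.911 with an estimated correlation), with NDUFA10 at 0.35. In all 1883 genes were called, 870 higher and 1013 lower in M, 239 and 345 of them at least 2-fold, with a median absolute change of 0.639. The count was 1160 without M brain 1, 1067 without M brain 2, 1212 without S brain 2 and 1133 without S brain 4. The other 33 lists did not pass.

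Both lines shared 699 genes called in brains with the same sign, 428 higher and 271 lower, and 15 with opposite signs. The shared genes with the smallest p were those of photoreceptors, among them saga, rbp3, PDE6H, PDE6C, rdh5 and unc119c, with ppdpfa, GNG11 and CAP1. Independent lists of these sizes would share 97.66 genes, a value that leaves out the shared WT libraries. In 20 simulations of unchanged groups against the same WT libraries the shared count was 0, which leaves out the effects and sets no baseline for lists that hold them. The fold changes of both lines had a Pearson correlation of 0.388 across genes (covariance 0.184), against means of 0.137 and 0.0136 in the simulations. Genes are not independent replicates, and part of the shared count can come from the shared WT libraries. The shared count was 425 without WT brain 2, 317 without WT brain 3 and 459 without M brain 3.

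In M bodies transcripts of the ovary and of cell division were lower, and those of digestive enzymes higher. Of these lists, cell division had adjusted p = 0.349 with an estimated correlation, and ovary and pancreas had adjusted p = 0.809 with an estimated correlation. The oocyte kinase MOS went from 22 ± 13.2 CPM (SD, n = 6) in WT to 0.318 ± 0.258 in M, a log2 change of -6.085 (SE 0.754, adjusted p = 3.56e-05), and WEE2 fell by 6.41, the ovarian factor zglp1 by 7.43 and the egg-coat gene zp3d.1 by 5.45. The replication genes MCM4 (-1.78), MCM2 (-1.33) and PCNA (-1.33) fell, as did the mitotic kinase aurka (-4.125), the checkpoint kinase chek2 (-3.13) and brca2 (-1.62). Among WT bodies the summed cell division genes rose and fell with the ovary score, as given below. The pancreatic genes ela2 (2.03), ctrb.1 (1.83) and CPA1 (2.12) rose, CPA1 from 835 ± 726 to 3630 ± 1020 CPM, and so did the muscle myosins smyhc1 (1.29) and myhz2 (1.06). The largest named rise was that of mhc2dab, a gene of the class II histocompatibility family, from 0.0313 ± 0.0485 to 88.4 ± 37.2 CPM, 2830 times (95% counting interval 783 to 23400). The keratin gene cyt1 rose by 4.42 (SE 0.392, adjusted p = 2.14e-06), capn2l by 1.83, IQSEC1 by 1.76, FBLIM1 by 1.31, mkrn1 by 1.03, DEDD2 by 0.85, SLC16A1, a transporter of lactate, by 0.77 and DUSP7 by 0.73. ANXA6 fell from 78.7 ± 22.1 to 0.129 ± 0.117 CPM, by 9.11 (SE 0.327, adjusted p = 2.1e-12). Also lower were the glycolytic enzyme GPI (-3.51), MYOF (-2.33), the glutathione transferase GSTM3 (-3.15), CTH, of cysteine synthesis (-2.64), USP48 (-1.765), cdca7b (-2.81) and SPART (-7.13). The gene taco1 had 0 counts in all 6 M bodies, at least 244-fold lower than the 12 ± 5.13 CPM of WT, while elovl8b was 253 times lower (95% counting interval 86.1 to 1230), hsd3b2, of steroid synthesis, 332 times (91.6 to 2750), the channel gene KCNS3 302 times (103 to 1470) and PCTP 143 times (25.4 to 5700). Intervals and bounds of this kind cover counting error only.

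The ovary list fell in all 34 of 34 measured members in M bodies (34 adjusted over the list alone; adjusted p = 2.91e-14, and adjusted p = 0.809 with an estimated correlation), with a median of -7.69 and a sum of 9246 ± 5700 CPM in WT against 44.52 ± 71.7 in M. Cell division fell in 38 of 42 (40 adjusted over the list alone, adjusted p = 4.65e-25, and adjusted p = 0.349 with an estimated correlation), with a median of -1.82 and a sum of 2380 ± 1120 against 582.5 ± 37.8 CPM. Among WT bodies this sum followed the ovary score, from 3600 CPM in WT body 1 (score 1.51) to 998 in WT body 6 (0.723). The fall in cell division therefore cannot be told apart from the fall in ovary content. Pancreatic genes rose in 16 of 25 and fell in 1 (18 and 1 adjusted over the list alone; adjusted p = 3.21e-07, and adjusted p = 0.809 with an estimated correlation), with sums of 14810 ± 12300 and 49090 ± 13700 CPM. Chaperones fell in 19 of 29 and rose in 2 (20 and 3 adjusted over the list alone; adjusted p = 8.81e-05, and adjusted p = 0.349 with an estimated correlation), with hsp90aa1.1 at -1.73. Genes of the unfolded protein response fell in 15 of 30 and rose in 3 (16 and 3 adjusted over the list alone; adjusted p = 0.00704, and adjusted p = 0.809 with an estimated correlation), with HSPA5 at -1.72. Those of p53 and DNA damage fell in 9 of 31 (9 adjusted over the list alone; adjusted p = 0.00785, and adjusted p = 0.349 with an estimated correlation). Ribosomal proteins rose in 16 of 78 (11 adjusted over the list alone; adjusted p = 0.000272, and adjusted p = 0.809 with an estimated correlation), with RPS2 at 0.36 and RPL22L1 at 0.60. Neurodevelopmental disease genes rose in 10 of 59 and fell in 4 (8 and 3 adjusted over the list alone; adjusted p = 0.00226, and adjusted p = 0.809 with an estimated correlation), with nrxn1b at 1.53 and scn1laa at -1.60. Markers of neurons (median 0.756, not passed at adjusted p = 0.053) and of glia (median 0.457; adjusted p = 0.0313, and adjusted p = 0.809 with an estimated correlation) moved with them, and gh1 was near 0 in 3 WT and 2 M bodies. Without those 5 bodies the median of the neurodevelopmental genes went from 0.53 to 0.355. In the testis list 6 of 18 fell (6 adjusted over the list alone; adjusted p = 0.0363, and adjusted p = 0.809 with an estimated correlation), with SYCP1, a gene of meiosis in both sexes, at -5.50 and CYP17A1, of steroid synthesis, at -3.70. The testis call was lost without M body 3 (adjusted p = 0.0502). Alcohol metabolism did not pass as a list, with 1 member higher and 8 lower of 34, ALDH18A1 among them at -1.70 and aldh9a1b at -0.95.

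In M bodies 6696 of 20240 genes were called, 2505 higher and 4191 lower, with a median absolute log2 change of 0.75, and 547 and 1768 of them changed at least 2-fold. With the ovary score of each library as a covariate 38 genes were called, and 2423 were called without the 5 bodies in which the growth hormone gene gh1 was near 0 (WT bodies 1, 2 and 5, M bodies 2 and 5). Of 41 lists 20 passed, 14 higher and 6 lower.

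In S bodies genes of the ovary, cell division and sterol synthesis were lower, each list with adjusted p = 0.86 with an estimated correlation. MOS fell by 4.24 (SE 0.635, adjusted p = 0.000159), from 22 ± 13.2 CPM (SD, n = 6) to 1.12 ± 1.4, and the log2 change was -3.91 for WEE2, -4.35 for zp3d.1 and -4.705 for zp3d.2. The mitotic kinases aurka (-3.71) and AURKB (-2.36), PRC1 (-2.47) and MCM4 (-1.40) fell too. In the sterol pathway MVK fell by 1.56, NSDHL by 1.62, insig1 by 1.09 and the receptor gene ldlra by 0.79. Among the genes that rose, KYAT3 was 203 times its WT level (95% counting interval 55.9 to 1680) and cyp2x10.1 588 times (105 to 23300). The keratin gene cyt1 rose by 4.99 (SE 0.4, adjusted p = 3.33e-07), ms4a17a.16 by 3.45, cyp2p7 by 2.56, the class II gene mhc2d4b by 2.07, ms4a17a.11 by 1.47, GPI by 1.41, DHDH by 1.23, cyp2n13 by 1.18, TTC14 by 1.055, the tetraspanin cd9a by 1.05 and the globin gene hbae5 by 2.501, while the globin hbaa1 fell by 0.71. Lower in S bodies were parp9, from 15.5 ± 3.05 to 0.725 ± 0.219 CPM (-4.39, SE 0.267, adjusted p = 4.2e-09), MIOX, of inositol breakdown (-5.06), thy1 (-4.74), tmprss4b (-6.08), the plasminogen activator PLAU (-3.78), the interferon-induced gene gbp3 (-2.66), GSTM3 (-2.12), brms1la (-1.495), USP48 (-1.43), NGEF (-1.10) and FLII (-0.83).

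The ovary list fell in 32 of 34 members in S bodies (34 adjusted over the list alone; adjusted p = 6.01e-10, and adjusted p = 0.86 with an estimated correlation), with a median of -4.24 and a sum of 483.7 ± 824 CPM. The ovary score was 0.678 in S body 2 and 0.283 in S body 3, and -0.572 to -1.01 in the other 4, where M bodies ran from -0.188 to -1.02. The egg-coat gene zp2.1 stood at 202 and 79.7 CPM in those 2 and at 0 to 1.15 CPM in the others. Cell division fell in 36 of 42 (37 adjusted over the list alone, adjusted p = 4.64e-15), with a sum of 774.2 ± 167 CPM, highest in S bodies 2 (1040) and 3 (898). Sterol synthesis fell in 15 of 25 (18 adjusted over the list alone; adjusted p = 1.66e-05). Both had adjusted p = 0.86 with an estimated correlation. Pancreatic genes summed to 28990 ± 7220 CPM, with 2 of 25 higher (0 adjusted over the list alone; adjusted p = 0.000443, and adjusted p = 0.86 with an estimated correlation), cela1.5 at 4.49 among them. Neurodevelopmental disease genes rose in 22 of 59 and fell in 3 (24 and 4 adjusted over the list alone; adjusted p = 0.000443, and adjusted p = 0.86 with an estimated correlation), such as AUTS2 (0.80) and nrxn1b (1.11). Of glutamate signalling 6 of 36 rose (0 adjusted over the list alone; adjusted p = 5.71e-05, and adjusted p = 0.86 with an estimated correlation), with GRIN2C at 1.355. Of neuropeptides 8 of 26 rose and 1 fell (8 and 1 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.86 with an estimated correlation), with sst1.2 at 1.22 and PYY at -0.65. Alcohol-responsive receptors and channels rose in 5 of 29 (4 adjusted over the list alone, adjusted p = 0.00586, and adjusted p = 0.86 with an estimated correlation), with GLRA1 at 0.93, CREB1 at 0.98, CNR1 at 1.13 and CRHBP at 0.66. Over all genes 3178 of 20240 were called higher in S bodies. That share is much like those of the glutamate and alcohol-responsive lists and above that of the pancreatic list. Markers of neurons (median 0.958) and of glia (0.531) moved with these lists, each with 6 members higher and 1 lower of 15 and adjusted p = 0.86 with an estimated correlation. The gene gh1 was near 0 in WT bodies 1, 2 and 5 and in no S body. Without the 5 bodies low in gh1 the median went from 1.12 to 0.435 for glutamate signalling, from 0.71 to 0.339 for neuropeptides. It went from 0.585 to 0.232 for neurodevelopmental genes, from 0.693 to 0.248 for alcohol-responsive genes and from 0.958 to 0.423 for neuron markers. How much nervous tissue each body held is not labelled, so the level per cell is not known. Alcohol metabolism had 7 of 34 higher and 8 lower and did not pass (adjusted p = 0.859), with cyp2p10 at -2.14. Genes of p53 and DNA damage fell in 12 of 31 and rose in 2 (12 and 2 adjusted over the list alone; adjusted p = 0.0109, and adjusted p = 0.86 with an estimated correlation), with mdm2 at -0.88. Cytoskeleton genes rose in 12 of 40 and fell in 5 (16 and 5 adjusted over the list alone; adjusted p = 0.0132, and adjusted p = 0.86 with an estimated correlation), with CLASP1 at 0.50 and MAPRE1 at -1.39.

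In S bodies 7445 genes were called, 3178 higher and 4267 lower, with a median absolute log2 change of 0.785, and 1007 and 1672 of them changed at least 2-fold. With the ovary covariate 212 genes were called, and without the 5 bodies low in gh1 3091. Of 41 lists 16 passed, 11 higher and 5 lower, and each of them had adjusted p = 0.86 with an estimated correlation.

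**Figure D4:**
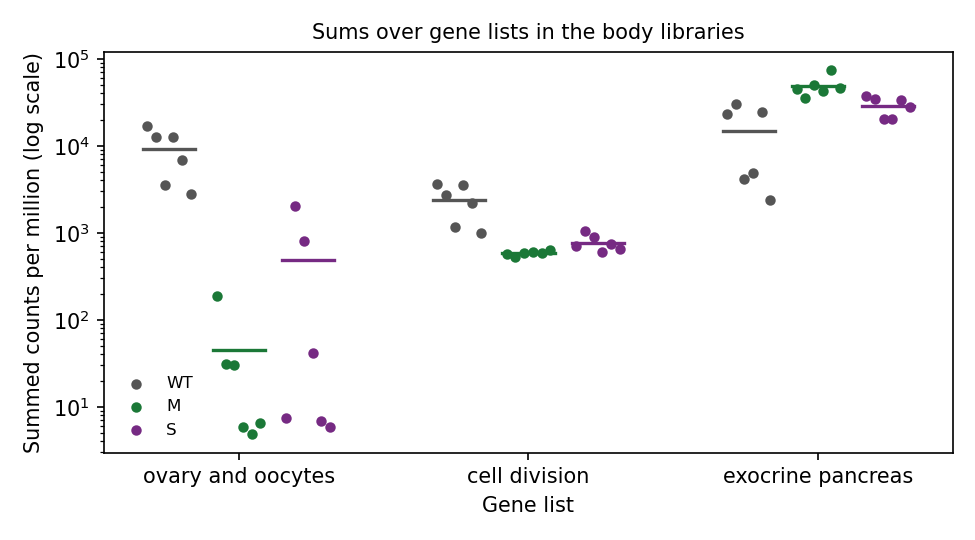
Summed CPM of the ovary, cell division and exocrine pancreas lists in each body library, on a log axis. Means of the ovary sum are 9246 CPM in WT, 44.52 in M and 483.7 in S, with a wide spread within each group.

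Between M and S bodies the ovary genes had a median log2 change of -3.45, lower in M. Of 34 members 1 was called lower (21 adjusted over the list alone; adjusted p = 0.0117, and adjusted p = 0.951 with an estimated correlation), a list call lost without M body 4 (0.0533), S body 2 (0.305) or S body 3 (0.106). GPI was lower in M (-4.92, SE 0.167, adjusted p = 2.56e-13), at 2.36 ± 0.53 CPM against 71.4 ± 8.26 in S (SD, n = 6), as were ANXA6 (-9.43), ms4a17a.16 (-3.35) and THUMPD3 (-1.46). KYAT3 was 193 times lower (95% counting interval 53.1 to 1600) and elovl8b 138 times (46.9 to 672). Higher in M were mhc2dab (8.92, SE 0.477, adjusted p = 8.72e-10), parp9 (4.52), MIOX (4.73), the endocytic receptor gene lrp2b (2.25), capn2l (2.03) and the clock gene CRY1 (1.245). Of 40 interferon-response genes 5 were higher and 1 lower (7 and 1 adjusted over the list alone), with tapbp.1 at 1.15. Of 23 macrophage genes 3 were higher (6 adjusted over the list alone), with ctss2.2 at 1.32. Both lists had adjusted p = 0.00271, and adjusted p = 0.951 with an estimated correlation. Ribosomal proteins were higher in 6 of 78 (8 adjusted over the list alone; adjusted p = 1.81e-06), with RPL24 at 0.45. Sterol genes were higher in 2 of 25 (8 adjusted over the list alone; adjusted p = 0.000409). Both had adjusted p = 0.951 with an estimated correlation. Chaperones were lower in 6 of 29 and higher in 1 (10 and 2 adjusted over the list alone; adjusted p = 0.0117, and adjusted p = 0.951 with an estimated correlation), with HSPB1 at -0.60. In all 1642 genes were called, 871 higher and 771 lower in M, 321 and 367 of them at least 2-fold, with a median absolute change of 0.835. Of 41 lists 11 passed, 7 higher and 4 lower.

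Both lines shared 4533 genes called in bodies with the same sign, 1427 higher and 3106 lower, and 65 with opposite signs. Those with the smallest p were cyt1, which rose, and tmprss4b, gbp3, GSTM3, USP48, PLAU, KCNS3, DCLRE1A, lmo7b and st3gal1, which fell; DCLRE1A, a DNA repair gene, fell by 2.15 in M and 1.99 in S. Independent lists would share 1277 genes, a value that leaves out the shared WT libraries. The count of 0 in 20 simulations of unchanged groups sets no baseline here either. The correlation of fold changes across genes was 0.743 (covariance 0.885), against means of 0.0386 and 0.00243 in the simulations. Genes are not independent replicates. When the 6 WT bodies were split so that each line had its own 3, in 20 such splits, 1625 to 2541 genes were shared and the correlation was 0.589 to 0.708. With the ovary covariate 11 genes were shared, and 1366 without the 5 bodies low in gh1.

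For genes on chromosome 8, which carries ccser1, no difference in the share of calls passed in the 4 tests of the whole chromosome. In brains 55 of 561 such genes were called in M against 1276 of 12345 on other chromosomes (odds ratio 0.943, 95% interval 0.696 to 1.26, p = 0.723, Fisher's exact test, two-sided), and 68 were called in S against 1234 (1.24, 0.943 to 1.62, exact p = 0.114). In bodies it was 0.929 in M (0.779 to 1.11, exact p = 0.41) and 0.94 in S (0.79 to 1.12, exact p = 0.494). The 4 tests are 1 family, and no unadjusted p of the 4 lay below 0.05. Without WT brain 2 the odds ratio in S brains was 1.39 (exact p = 0.0423), and for the 100 genes nearest to ccser1 it was 1.47 in S brains (exact p = 0.181) and 0.631 in M bodies (exact p = 0.0463). The share of calls within 5 Mb of ccser1 was not analysed here.

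The difference between each line and WT was not the same in body and brain for many genes. The ovary covariate was not used in this test, so the ovary difference of the bodies can enter its counts. In M the cerebellin gene cbln13 was 76.3 times lower in brain (95% counting interval 25.6 to 374) and stood at 0.24 in body (adjusted p = 3.7e-06 for the difference), and the myelin gene cldnk one of 1.59, with a fall of 1.33 in brain alone. The nuclease gene FAN1 rose by 1.07 in brain and fell by 1.49 in body, a difference of -2.60 (SE 0.308, adjusted p = 3.12e-05), and MCM7 rose by 1.68 in brain and fell by 1.12 in body. In S nepro rose by 2.47 in brain and fell by 1.37 in body, a difference of -3.895 (SE 0.431, adjusted p = 8.21e-06), PTK2B rose by 4.196 in brain and 1.14 in body, and atp5mj, of the ATP synthase, fell by 0.47 in brain and rose by 0.43 in body. The test called 2767 of 22442 genes in M, 816 with a more positive change in body and 1951 with a more negative one, and 2057 in S, 617 and 1440. The counts were 1287 and 623 without the 7 libraries that stood apart, and with DESeq2 the S count was 3112. The S count was 1041 without WT brain 2, 1169 without WT brain 3 and 3439 without WT body 6.

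Some differences between the lines were alike in both tissues. Between M and S 1883 genes were called in brain and 1642 in body, and most calls of a tissue were not made in the other. Of the 299 genes called between M and S in both brain and body, 278 had the same sign, and 74 differed at least 4-fold in both. ANXA6 had log2 values of -7.14 in brain and -9.43 in body. PCTP had 0 counts in M brains, at least 36.6-fold lower than in S, and was 157 times lower in M bodies (95% counting interval 27.9 to 6250). The class II gene mhc2dab was 1830 times higher in M brains (506 to 15100) and higher by 8.92 in M bodies.

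**Figure D5:**
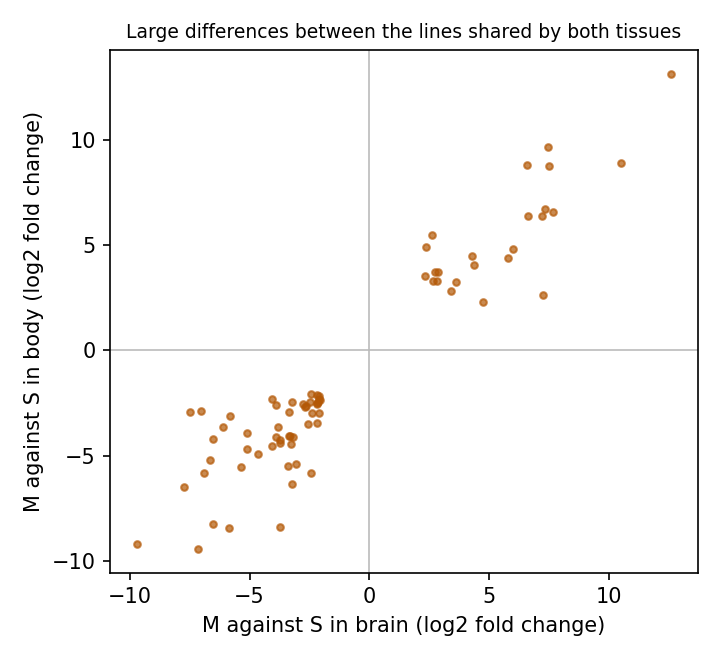
Log2 difference between M and S in brain (horizontal) and in body (vertical) of the 74 genes that differ at least 4-fold with the same sign in both tissues, 24 higher and 50 lower in M.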

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

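The 3 tests on the photoreceptor genes, and the tests of less ovary and of scaling, were chosen after the results were seen; the ovary covariate and the splits were chosen beforehand.

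Of 100 groups of list sums, 6 had a library far from the others of its group, where 5 are expected by chance, about 1 in 20 groups. Glia genes summed to 5453 CPM in M brain 4, against 4452 to 4524 in the other M brains. Photoreceptor genes summed to 206.4 CPM in S brain 2, against 384.2 to 398.8 in the other S brains. In S brain 3, skeletal muscle genes summed to 1362 CPM, against 90.3 to 95.26, and epidermis genes to 5086 CPM, against 238 to 258.5. The number expected by chance does not cover gaps of this size. Liver genes summed to 33630 CPM in S body 4, against 26540 to 27450, and pigment cell genes to 132.7 CPM in WT body 5, against 105.3 to 107.6. No explanation of these sums was tested.

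The change between body and brain differed for 2767 genes in M and 2057 in S, by an interaction test. In M the difference, body minus brain, was 6.22 for cbln13 (a fitted value, with 3 counts in M brains), 1.47 for one of the genes listed as HTRA1 (-0.81 in brain, 0.69 in body), 2.82 for cyp2p7 (-2.335 in brain), 1.59 for cldnk, 5.69 for urp2 (-4.63 in brain, not tested in body) and 1.045 for mkrn1 (1.03 in body). It was -1.81 for USP48 (-1.765 in body), -2.60 for FAN1, -2.835 for ppdpfa (2.48 in brain), -2.83 for MCM7 and -3.03 for the glutamate receptor gene GRIK1 (-3.125 in body). In S it was 4.94 for cbln13 (-5.15 in brain), 3.36 for acbd4 (3.43 in body), 0.84 for atp5mj, 2.92 for the transporter gene SLC5A11 (-2.97 in brain), 1.196 for cd9a and 2.39 for cyp2p7 (2.56 in body). It was -6.79 for parp9 (-4.39 in body), -3.895 for nepro, -3.12 for one of the genes listed as PTK2B, -5.12 for PDE6C (4.365 in brain, not tested in body), -2.765 for ppdpfa (2.24 in brain) and -4.435 for rdh5 (4.48 in brain, 0.09 in body). In 1 of 100 splits, the real one, as many genes were called in M (2767, highest other 2199) and likewise in S (2057, highest other 1730). No other split tried reached either count, which does not exclude a chance imbalance of an unlabelled factor, such as sex.

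Photoreceptor genes were higher in the brains of both lines. A list of retina genes, most of them outside the photoreceptor cascade, was written for this test. It also held cone opsins and lens genes such as BFSP1 and CRYBA4. Of its 32 measured members 3.12%, rlbp1a, were at least 2-fold higher in both lines with mutant means of at least 0.5 CPM. With no such minimum 5 were, among them the cone opsins opn1lw1, at 0, 0.259 and 0.539 CPM, and opn1lw2, at 0, 0.237 and 0.433. The list summed to 95.6 CPM in WT, 93.9 in M and 106 in S. Of its members 6 are also in the photoreceptor list, and WT brains held 15 at 0.5 CPM or more. Among its members RGR was at 15.8, 18 and 20.3 CPM and cabp5b at 11.4, 5.59 and 6.03. A little retina need not bring lens or lift genes that brain already holds, so this share does not decide on retina tissue. The lowest median of the photoreceptor list with 1 brain library left out was 3.219, which argues against a single library. Of 6 measured genes of a pineal gland list, 66.7% were at least 2-fold higher in both lines with the same minimum (5 with none), aanat2 (1.04 CPM in WT, 9.76 in M, 7.52 in S), ASMT (0.756, 17.6, 19.9), parapinopsinb and parietopsin, while asmt2 was not (10, 7.42, 8.17); none is in the photoreceptor list, and WT brains held 3 at 0.5 CPM or more. So more pineal gland in the mutant than in the WT brain libraries, through dissection or through biology, stays open and may account for the rise. Retina tissue is not excluded either, and a change of expression within pineal cells was not tested.

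Ovary genes were lower in the bodies of both lines. A single component held 97.8% of the variance of the ovary genes among the WT bodies, so ovary content already differed within WT; scaled by totals without the 13 most abundant genes, the ovary median was -4.15 in S and -7.71 in M, against -4.24 and -7.69, which argues against scaling by a few abundant genes. With the ovary score as a covariate, 2.85% of the calls were left in S and 0.568% in M, while the median absolute change went from 0.785 to 0.429 in S and from 0.75 to 0.371 in M, and the median SE rose from 0.2 to 0.331 and from 0.186 to 0.361. The score separates the WT bodies from all mutant bodies, with the lowest WT body at 0.723 and the highest mutant body, S body 2, at 0.678, so the covariate removes part of any change due to the lines too. Fewer or less mature females among the mutant bodies, which the unlabelled sex leaves open, and a smaller ovary in mutant females are both candidate explanations, and no test here separates them. In the testis list 0 of 18 members were called higher, with 6 lower in M and 5 in S, so no rise of testis genes was seen. Members such as SYCP1 belong to meiosis in both sexes, so this does not settle the sex of the fish. The vitellogenin gene vtg1, chosen after its values were seen, was at 0.0944 CPM in WT, 0.0684 in M and 0.0159 in S. Near 0 in all groups, it cannot tell mature females apart.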

How the results depend on the processing

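Chosen after the data were seen were the fits without libraries that stood apart and the 100 nearest genes. DESeq2 called 1886 of the 1895 genes of M brains, 1925 of 1935 of S brains, 6681 of 6696 of M bodies and 7401 of 7445 of S bodies. RLE factors, no filter, a filter at 1 CPM and a fit that is not robust left every count of genes within 1.5 times its value, and DESeq2 did so for all but the S difference between tissues, 3112. The ovary covariate gave the lowest counts in bodies against WT: 38 in M, 212 in S and 11 in both. The odds ratio for the ccser1 chromosome was then 2.38 in M (Fisher's exact p = 0.223) and 0.353 in S (exact p = 0.182). As built, the covariate takes up the difference in ovary genes. Without the 5 bodies low in gh1 the counts were 2423, 3091 and 1366, and without 7 libraries 1287 and 623 for the differences between tissues; fewer samples entered these fits. With only WT and M in the fit 1186 genes were called in M brains. The odds ratio of the 100 nearest genes was 0.631 in M bodies (Fisher's exact p = 0.0463). The cause of the other shifts was not tested.

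Called genes that also changed at least 2-fold numbered 421, 373 and 584 in brains (M against WT, S against WT, M against S) and 122 in both lines, and 2315, 2679, 688 and 1536 in bodies. With the replicate number as a block the counts were 1544, 1352 and 1588 in brains and 6669, 7945 and 1445 in bodies.

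With each library left out in turn, counts in brains ran from 1060 (without WT 3) to 2590 (without M 4) in M, from 895 (without WT 3) to 2270 (without M 4) in S, from 1067 (without M 2) to 2482 (without M 4) between the lines and from 317 (without WT 3) to 839 (without M 4) in both. The odds ratio of the ccser1 chromosome ran from 0.685 to 1.06 in M brains, 1.08 to 1.39 in S brains (exact p = 0.0423 without WT 2) and 0.884 to 1.01 in S bodies, and the S difference between tissues from 1041 (without WT brain 2) to 3439 (without WT body 6) genes. The adjusted p of the immediate early list in M brains ran from 0.00181 to 0.167, and its direction reversed without M brain 4. Signs that changed belonged to values near 0: CCSER2 in brains, -0.004522 to 0.07598 in M, -0.01575 to 0.06029 in S and -0.02027 to 0.06328 between the lines, ccser2b in M bodies, -0.1566 to 0.1092, and CCSER1 between the bodies of the lines, -0.07451 to 0.2214.

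Without M brain 4 and S brain 3, CCSER2 was at -0.004007 in M brains and -0.01738 between the lines. With the ovary covariate the sign reversed in M bodies for CCSER2 (-0.1606), pnocb (-0.0058), SV2C (-0.1508), crp2 (0.1531), hsd3b2 (0.36), PHEX (0.1558), acana (-0.007541), SOX10 (-0.01577), zp3d.1 (0.5232), SPATA18 (0.01373) and epcam (0.1295), in S bodies for NR3C1 (-0.05247), pde6ha (0.5815) and zp3d.2 (0.256), and between the lines for CCSER1 (-0.03133). Lists also reversed with that covariate: in M bodies alcohol-responsive genes (adjusted p = 0.876), clock (0.0954), skeletal muscle (0.12) and ovary (0.0182), in S bodies skeletal muscle (0.598) and ovary (0.00344), and between the lines ovary (0.798).

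Of 47 list calls in bodies 18 held with the ovary covariate, 19 with fry and 0 with an estimated correlation; of 29 in brains 22 held with fry and 2 with an estimated correlation. Of 335 values of named genes in brains 330 kept their direction and side of the threshold with DESeq2, and of 443 in bodies 421 with DESeq2, 148 with the ovary covariate and 303 without the 5 bodies low in gh1. Of the 3685 and 7974 values with 1 library left out 3264 and 7412 did. The window of 5 Mb around ccser1 was not run. At the depths and group sizes here a self-test on simulated changes recovered 81.6% to 94.9% of genes changed 4-fold within a tissue, and 27.6% of those whose change differed 2-fold between tissues.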

Other observations

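The gene order and odds ratio tests below, and the splits, were chosen beforehand; the growth hormone gene gh1 was chosen after its values were seen.

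Lists of less weight in the report also passed in brains. In M brains immediate early genes had 1 member higher and 5 lower of 32 (2 and 9 adjusted over the list alone, adjusted p = 0.0299, and adjusted p = 0.614 with an estimated correlation), with NR4A3 at -0.89 and klf2a at -0.84. The call was lost without WT brain 1 (0.0669) or 2 (0.167), and the direction reversed without M brain 4 (0.0932). These genes summed to 2840, 2940 and 2890 CPM in M brains 1, 2 and 3, above every WT brain (1820 to 2460). In M brain 4 they summed to 1170 CPM. Glycolysis had 3 higher and 6 lower of 33 (4 and 10 adjusted over the list alone; adjusted p = 0.0299, and adjusted p = 0.466 with an estimated correlation), with LDHA at -0.38 and pgam1a at -0.48; the call was lost without WT brain 2 (0.069) or 3 (0.105) or M brain 1 (0.06). Cell division had 1 higher, MCM7 at 1.68, and 2 lower of 39 (adjusted p = 0.0322, and adjusted p = 0.416 with an estimated correlation), a call lost without WT brain 2 (0.107) or M brain 2 (0.109). Interferon genes had 2 higher, IFIH1 at 2.865 and tapbp.1 at 1.05, and 1 lower of 32 (adjusted p = 0.00704, and adjusted p = 0.614 with an estimated correlation), a call lost without WT brain 2 (0.0507) or 3 (0.0715) or M brain 1 (0.06). Glutamate signalling had 2 higher of 37, grin2db at 0.73 and GRIA1 at 0.51 (adjusted p = 0.00862, and adjusted p = 0.381 with an estimated correlation), a call lost without WT brain 1 (0.0623).

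In bodies, neuron markers and the gene gh1 varied between libraries of a group, which was not tested. Neuron markers summed to 342 to 686 CPM in WT bodies, 257 to 861 in M and 589 to 804 in S. The gene gh1 averaged 6 CPM in WT, 7.89 in M and 7.54 in S and was near 0 in WT bodies 1, 2 and 5 and M bodies 2 and 5. In M bodies muscle genes were higher in 7 of 27 and lower in 2 (9 and 2 adjusted over the list alone; adjusted p = 0.0363, and adjusted p = 0.809 with an estimated correlation), with myhz1.3 at 1.45; the call was lost without WT body 1 (0.0623) or 4 (0.118) or M body 5 (0.112). Clock genes were higher in 15 of 41 and lower in 3 (15 and 5 adjusted over the list alone; adjusted p = 0.0486, and adjusted p = 0.809 with an estimated correlation), with PER3 at 0.82 and cry4 at -0.95; of the fits with 1 library left out, 10 lost this call, with 0.11 without WT body 2 the highest. Synaptic genes had 3 of 31 higher in S bodies (0 adjusted over the list alone; adjusted p = 0.000529, and adjusted p = 0.86 with an estimated correlation), with CPLX2 at 0.92, and neuron markers 6 higher and 1 lower of 15 (8 and 1 adjusted over the list alone; adjusted p = 0.00586, and adjusted p = 0.86 with an estimated correlation), with RBFOX3 at 1.16 and UCHL1 at -2.10.

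Other lists passed in M bodies with few called members, each with adjusted p = 0.809 with an estimated correlation. Neuron markers, with 2 members higher and 1 lower of 15 and a median of 0.756, did not pass (0.053), and gh1 was near 0 in 3 WT and 2 M bodies. Without those 5 bodies the median went from 0.504 to 0.294 for alcohol-responsive genes, from 0.919 to 0.712 for glutamate signalling, from 0.693 to 0.598 for neuropeptides and from 0.756 to 0.53 for neuron markers. Alcohol-responsive receptors and channels had 1 of 29 higher (0 adjusted over the list alone; adjusted p = 0.0231), a call lost without WT body 1 (0.0509) or M body 6 (0.0514). Glutamate signalling had 0 of 36 called (0.00226), GABA signalling 1 of 23 higher, GAD1 at 0.83 (0.0145), synaptic genes 1 of 31 lower, nsfb at -0.32 (0.00662), and neuropeptides 3 of 26 higher, sst2 at 0.80 among them (0.0313, lost without M body 6 at 0.0614). Glia markers were higher in 4 of 15, such as SLC1A3 at 0.46 (0.0313, lost without M body 6 at 0.0514). Innate immune genes were higher in 10 of 35 and lower in 1, with PTGS2 at 1.01 (0.0406, lost in 14 fits with 1 library left out, with 0.177 without M body 2 the highest). Macrophage genes were higher in 6 of 23 and lower in 1, with SPI1 at 0.83 (0.0416, lost in 7 such fits, with 0.129 without WT body 6 the highest), and epidermis genes higher in 5 of 24 and lower in 1, with krt91 at 0.69 (0.0406, lost in 5 such fits, with 0.112 without WT body 4 the highest).

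Between the lines, 74 genes differed at least 4-fold with the same sign in both tissues, 24 higher and 50 lower in M, such as mhc1uba (9320 times higher in M brains, 95% counting interval 1670 to 368000, and at least 2280-fold higher in M bodies), ddx43 (-4.08, -4.56) and iqcb1 (-2.70, -2.71). These 3 genes were chosen after their values were seen. Among the 31 with a known place in gene order, 3 pairs were neighbours, where 1000 random draws gave at most 1 and a mean of 0.073, and 10 lay on chromosome 4. Different haplotypes carried by the families of the lines are a candidate explanation for part of these differences, apart from any effect of ccser1. The odds ratio for the ccser1 chromosome was 0.738 (95% interval 0.0181 to 4.46, exact p = 1), so a role of the haplotype linked to ccser1 cannot be told apart from none with 1 such gene.

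Other splits of the same libraries into groups of the same sizes called fewer genes than the real split in brains: 1 of 35 splits, the real one, gave as many in M (1895, highest other 1168), in S (1935, highest other 14) and between the lines (1883, highest other 1), and 1 of 100 for both lines (699, highest other 55). No other split tried reached these counts, and 1 of 35 is the smallest share that all 35 splits can give. In bodies 2 of 100 splits gave as many genes in M (6696, highest other 7435), 1 of 100 in S (7445, highest other 6752), 1 of 100 between the lines (1642, highest other 15) and 1 of 100 in both (4533, highest other 0). These shares are small, but in M another split called more genes than the real one. They do not exclude a chance imbalance of an unlabelled factor, such as sex, between the groups. Splits of bodies that call as many as 7435 genes point to a structure of the samples that does not follow the groups alone.

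For the number of lists called, chance was not excluded in any comparison. In brains 5 of 35 splits gave as many lists in M (17, highest other 23), 28 of 35 in S (8, highest other 17) and 35 of 35 between the lines (4, highest other 17). In bodies 39 of 100 did in M (20, highest other 32), 55 of 100 in S (16, highest other 26) and 70 of 100 between the lines (11, highest other 28).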
